A study of Mus musculus with 17 samples.

How the data were processed

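RNA of mouse CD8 T cells was measured on 17 Illumina mouse arrays, 1 array per sample, with 45281 probes each. Per the labels' protocols, total RNA was extracted with QIAzol and a miRNeasy kit and turned into biotinylated cRNA for hybridisation. The scanner and its software are not given in the sources used here. The values of the non-normalized table are linear signal intensities as deposited by the authors, with no background subtraction and no log, per the file headers and the values. Detection p-values and control probes were not used here. A second deposited table, the authors' processed values, holds linear intensities as well. Set against the non-normalized signals, each of its columns kept the order of the probes (smallest Spearman correlation 1 over the 17 arrays) and held the same set of sorted values. These values were the means of the sorted signals to within 3.09, which is quantile normalization over the 17 arrays. The median of every column of the authors' table was 97.8. Its scale is linear, its columns hold single arrays and not ratios, and its genes were not centred, so none of scale, centring and direction stays unknown.

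Groups were taken from the labels: naive cells (n = 5), Teff (n = 5), Tpm (n = 4) and memory cells (n = 3). Arrays are named by their group and by the sample number in the labels, which runs from 1 to 17 through all groups. The groups share no numbers, so the numbers pair nothing. The label of Teff 8 names the spleen as its source, where the labels of the other Teff arrays name a coculture with splenic dendritic cells. It was kept with Teff, as its title states. No columns of the series were left unused.

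The background of each array was taken from the distribution of its own signals, because the planned correction with control probes or detection p-values could not be run on these values. The mode of the signals was the mean of the background and the root mean square of the signals below the mode was its SD. Signals were corrected by the normexp convolution model with these parameters, raised by an offset of 16, quantile normalized over the 17 arrays and put on a log2 scale. A probe counted as above background on an array when its signal lay over the mode by 2.326 SD, which stands for a one-sided p of 0.01. Probes above background on at least 3 arrays were kept. The remaining steps followed the plan, which was fixed, with the groups, the tests, the gene lists and most of the alternatives, before the data were examined.

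Probes were named through the platform's annotation table. There, 34885 probes had 1 gene symbol, 18 had several and 10378 had none, and 34807 of those with 1 symbol were matched to the reference gene table by their gene ID, which changed 0 symbols. Of 19131 probes kept, 16152 had 1 symbol, 11 had several and 2968 had none. Probes with several symbols or none stayed in the normalization and out of the counts of genes. A gene with several kept probes, as 3976 genes had, was represented by the probe with the highest mean over the 17 arrays. This left 10246 genes.

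Genes were tested with limma (version 3.58.1, R version 4.3.3): a linear model with 1 coefficient per group over all 17 arrays, moderated by empirical Bayes, two-sided, with Benjamini-Hochberg adjustment over the 10246 genes of each of 6 contrasts. A gene was called higher or lower at an adjusted p under 0.05 and a difference of at least 2-fold, which is 1 on the log2 scale. A gene stood apart in Tpm when it was called in the same direction against each of the other groups. All differences are on the scale of log2 of the corrected intensity plus 16, which understates the change of dim genes. A gene not above background on any array of the dimmer group has only a bound there. It is given as at least N-fold, which sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the gene's own value and the lowest value above background on that array. That lowest value lay between 4.69 and 5.06 on the log2 scale on 16 arrays and at 6.42 on memory 5.

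The plan held 33 gene lists with 623 genes, for T-cell states, signalling, metabolism, cell division, interferon responses and markers of other cell types. The 32 lists with at least 5 measured genes were tested against all other genes with camera of limma at a preset correlation of 0.01 between genes. Adjustment was over the 96 tests of the 3 main contrasts, and over the 96 tests of the other contrasts. The hepatocyte list had 4 measured genes and was not tested. Each test was repeated with a correlation estimated from the data. Of 34 list calls in the main contrasts, 9 held with it, and of 33 in the other contrasts 15 held. The enrichment of lists among genes that stood apart in Tpm was tested with the hypergeometric distribution over the 10246 genes.

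Genes are named by a rule fixed with the plan. It takes, in each main contrast, the 8 called genes with the largest difference in each direction among those above background on at least 1 array of both groups and with no overlap between the arrays of the groups. It adds the 4 genes in each direction with the largest at-least fold. From each list described it takes up to 4 called members with the largest difference. A set of 16 genes of T-cell states is named whether called or not, except for members that are not reported here. In the other contrasts it takes the 3 genes in each direction with the largest difference under the same limits on background and overlap, and among genes apart in Tpm the 8 in each direction with the largest smallest difference. RIKEN clones, predicted genes and antigen receptor segments were passed over in the picks by size and by fold. Genes outside the rule are said to have been chosen after their values were seen.

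The fit and the calls were tested on simulated normalized values of 10246 genes. Each gene had its naive mean in every group and independent noise of its spread within groups. In each contrast 100 genes were changed by 1.5 and 100 by 3 on the log2 scale. Background correction, normalization, filtering and the choice of probes were not tested, nor was variation shared between genes. For Tpm versus naive the fit called 80% of the former and 100% of the latter, with 2 false calls. For Tpm versus Teff the shares were 86% and 100%, with 5 false calls, and for Tpm versus memory 74% and 99%, with 5 false calls.

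The alternatives tried were no background correction, scaling of each array to the median in place of quantile normalization, the authors' table, no filter and a stricter filter on dim probes, the mean of a gene's probes, a fit of only the groups compared, a trended and robust prior, array weights, other thresholds, each array left out in turn, and for lists an estimated correlation, a rotation test and lists without shared genes. Another background correction, the sex pattern of the arrays as a covariate, the arrays numbered 12 to 17 against the others as a covariate, and leaving out both dim memory arrays were added after the data were seen. The closing section gives their effect.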

Results

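Gene expression was compared between CD8 T cells of 4 kinds from mice of C57Bl/6 background aged 2 to 6 months. All derived from OT-I mice, whose T cells carry a transgenic receptor for a peptide of ovalbumin (OVA). Naive cells were taken from the spleen (n = 5). Effector cells (Teff, n = 5) were activated by dendritic cells. The partial memory cells (Tpm, n = 4) were primed in coculture with liver sinusoidal endothelial cells (LSEC), which line the capillaries of the liver and can present antigen to T cells. Memory cells (n = 3) came from spleens 3 months after infection with Listeria monocytogenes that carried OVA. Nothing in the labels says that the arrays of a group came from separate mice or cultures, so p-values measure only the spread between these samples, part of which may be technical. By genes of the sex chromosomes, naive 13, Tpm 14 and Teff 17 had a male pattern and the other 14 arrays a female one, so the arrays of these 3 groups did not all come from the same mouse.

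The mean signal of 15 arrays lay between 227 and 471, and 31.6% to 37.4% of their probes were above background. Memory 3 (mean signal 140, 29.9% of probes) and memory 5 (96.7, 19.9%) were dimmer, with 7522 and 5408 genes above background against a median of 8308. The number of arrays limits the precision. Each array correlated best with the mean of its own group, with coefficients across genes from 0.929 for memory 5 to 0.990 for Teff 8. The first principal component, with 42.0% of the variance, ran from naive and memory cells over Tpm to Teff. A second component (16.9%) separated memory from naive cells, and the third (13.3%) set Tpm apart from the rest.

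**Figure D1:**
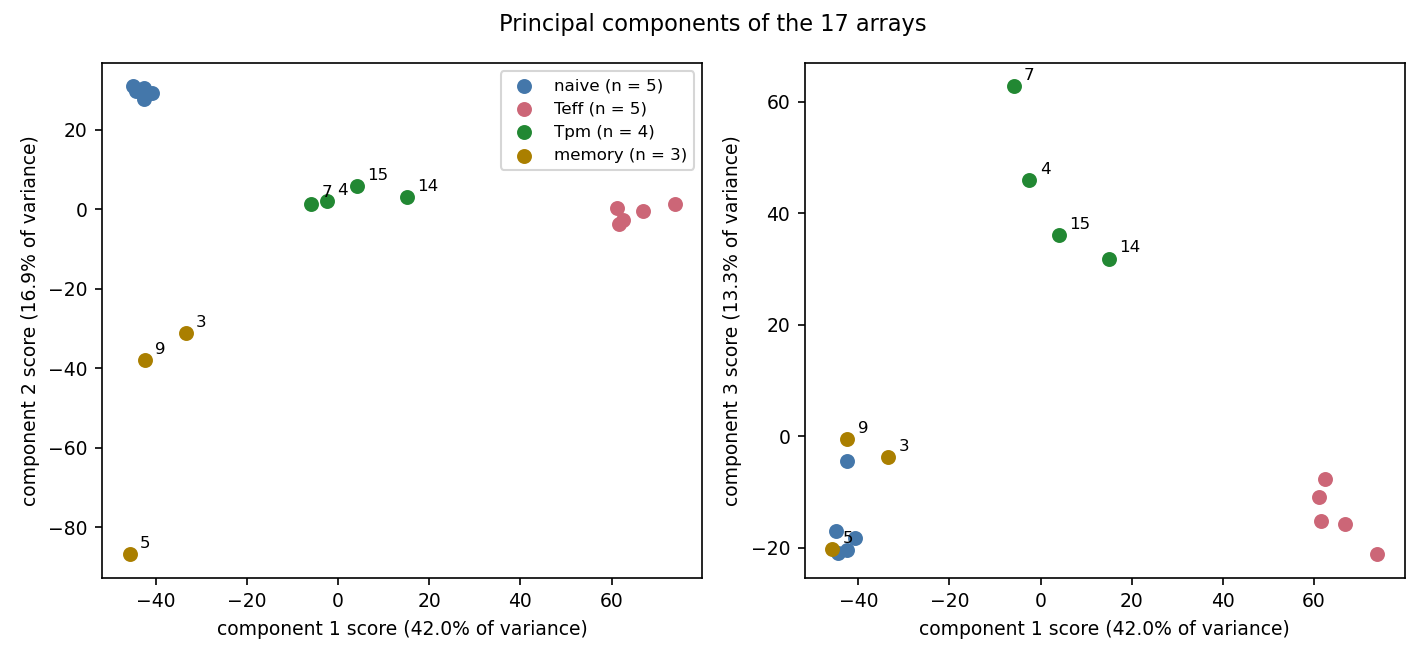
Scores of the 17 arrays on principal components 1 and 2 (left) and 1 and 3 (right), with the percentage of variance on each axis; each point is an array, coloured by group, and Tpm and memory arrays carry their number. The 4 Tpm arrays lie between naive cells and Teff on component 1, which holds 42.0% of the variance, and memory 5 lies farthest out on component 2.

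Among the genes with the largest rises from naive cells to Tpm were the chemokine Xcl1 and the inhibitory receptor Lag3. Xcl1, which attracts cross-presenting dendritic cells, rose from 5.97 ± 0.75 (SD, n = 5) to 11.78 ± 0.16 (SD, n = 4) on the log2 scale, by 5.81 (limma adjusted p = 1.63e-08). Lag3, a receptor for MHC class II that restrains T cells, rose by 5.81 (adjusted p = 9.51e-06). Of 15 genes of naive and quiescent T cells 10 fell, and this list kept its call with an estimated correlation (adjusted p = 0.029). Rises took in 13 of 18 cell division, 8 of 18 interferon-gamma response, 14 of 20 endothelial and 8 of 10 stromal genes, and falls 14 of 21 immediate early genes. These 5 calls were lost with an estimated correlation (adjusted p = 0.369, 0.0591, 0.0531, 0.0832 and 0.154). In all, 889 genes were higher and 511 lower in Tpm than in naive cells.

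Other large rises were those of genes above background on at least 1 naive array, though not always on all 5. They included the stem cell factor receptor Kit (5.50), the interferon-induced chemokine Cxcl9 (5.27) and the actin-associated protein Synpo (5.09). The protease inhibitor Serpina3f (4.85) and the zinc finger protein Hivep3 (4.11) were also among them. A second probe gave 0.89 for Kit and 0.76 for Hivep3. Ubd, a ubiquitin-like modifier induced by inflammatory cytokines, was not above background on any naive array and was at least 29.5-fold higher in Tpm, and Cables1 was at least 27.2-fold higher. Apart from haemoglobin genes, large falls were those of the AMP deaminase Ampd1 (-4.70), the MAP kinase phosphatase Dusp10 (-4.50), Ppp1r15a, a regulatory subunit of the phosphatase of the translation factor eIF2 (-4.45), the AP-1 subunit Fosl2 (-4.25), Pdlim4 (-4.10), Cd163l1 (-4.03) and the cyclic AMP-responsive factor Crem (-3.93). Ramp3 was at least 9.57-fold lower. Adjusted p-values for these genes lay between 1.04e-10 (Dusp10) and 0.00245 (Cd163l1). Without Tpm 14, Cd163l1 differed by -3.40 and Pdlim4 by -4.79.

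Of 15 measured naive and quiescence genes, 0 rose and 10 fell (camera adjusted p = 9.86e-10; adjusted p = 0.029 with an estimated correlation). They included the transcription factors Klf3 (-3.49) and Klf2 (-2.82), the latter a regulator of T-cell exit from tissues, as well as the interleukin-6 receptor gene Il6ra (-3.29) and Igfbp4 (-2.62). Of 21 immediate early genes, 14 fell and 3 rose (adjusted p = 2.25e-05; adjusted p = 0.154 with an estimated correlation). Junb fell by 3.58, the phosphatase gene Dusp5 by 2.94 and the chemokine receptor Cxcr4, from another list, by 3.19, whereas Ier3 rose by 3.05. Of 21 cytokine receptor genes 4 rose and 7 fell (adjusted p = 0.0134; adjusted p = 0.0789 with an estimated correlation), with rises of the interleukin-10 receptor gene Il10ra (3.09) and of Il12rb2 (2.08).

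Of 18 cell division genes 13 rose and 0 fell (adjusted p = 5.07e-05; adjusted p = 0.369 with an estimated correlation), with the mitotic kinases Plk1 (2.21) and Aurkb (1.92), the spindle factor Tpx2 (1.95) and Nusap1 (1.88). Their list mean over naive cells was highest in Tpm 14, at 2.27 against 0.76 to 1.22 on the other Tpm arrays. Of 25 DNA replication genes 7 rose and 1 fell (adjusted p = 0.00107; adjusted p = 0.134 with an estimated correlation), where the replication factor Mcm10 rose by 2.00 and the licensing factor Cdt1 fell by 1.56. Glycolysis genes followed, with 6 of 16 higher and 0 lower (adjusted p = 0.00536; adjusted p = 0.369 with an estimated correlation). Tpi1 rose by 2.46, Pgam1 by 1.24 and Pgk1 by 1.19. Of 17 genes of the amino acid response and one-carbon metabolism 6 rose (adjusted p = 0.0252; adjusted p = 0.424 with an estimated correlation), among them the asparagine synthetase gene Asns, at least 14.9-fold. This call was lost without naive 13 (adjusted p = 0.0535) and with the arrays numbered 12 to 17 set against the others as a covariate (adjusted p = 0.0538).

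Interferon-gamma response genes were higher, 8 of 18 with 0 lower (adjusted p = 1.55e-06; adjusted p = 0.0591 with an estimated correlation). Besides Cxcl9, the GTPase genes Igtp (2.19), Gbp3 (1.78) and Gbp2 (1.67) rose. Type I interferon response genes went the other way, with 0 higher and 7 of 21 lower (adjusted p = 0.00208; adjusted p = 0.442 with an estimated correlation). Oas2 was at least 5.37-fold lower, and Mx2 (-1.71) and Irf7 (-1.60) fell. The groups overlapped in the mean of the type I list. Naive 13 stood at -0.986, below every Tpm array (-0.871 to -0.464), and the other naive arrays at 0.020 to 0.444.

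The markers of other cell types that moved with Tpm were endothelial and stromal. Of 20 liver sinusoidal endothelial markers 14 rose and 0 fell (adjusted p = 1.2e-10; adjusted p = 0.0531 with an estimated correlation), and of 10 stromal and stellate cell markers 8 rose and 0 fell (adjusted p = 1.98e-07; adjusted p = 0.0832 with an estimated correlation). Igfbp7, a secreted protein abundant in endothelium, rose from 4.66 ± 0.25 (SD, n = 5) to 11.57 ± 0.32 (SD, n = 4), by 6.91 (adjusted p = 6.78e-07). No gene above background on at least 1 array of both groups rose more. Angpt2, an endothelial ligand of the receptor Tie2, was at least 38.2-fold higher, the matrix proteoglycan Bgn at least 22.5-fold, the basement membrane collagen Col4a1 at least 16.8-fold, Egfl7 at least 17.3-fold, Dcn at least 14.0-fold and Acta2 at least 12.2-fold, and Plvap rose by 3.67. Haemoglobin genes moved down: Hbb-bs fell by 7.69, Hbb-bt was at least 151-fold lower, Hba-a1 at least 112-fold and the red cell anion exchanger Slc4a1 at least 5.64-fold. Of 5 erythroid markers 3 fell (camera adjusted p = 0.00165, and 0.188 with an estimated correlation). This was not particular to Tpm: the mean of the erythroid list lay from -2.622 to -2.542 on the Tpm arrays. On the Teff arrays it lay from -2.464 to -2.324.

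**Figure D2:**
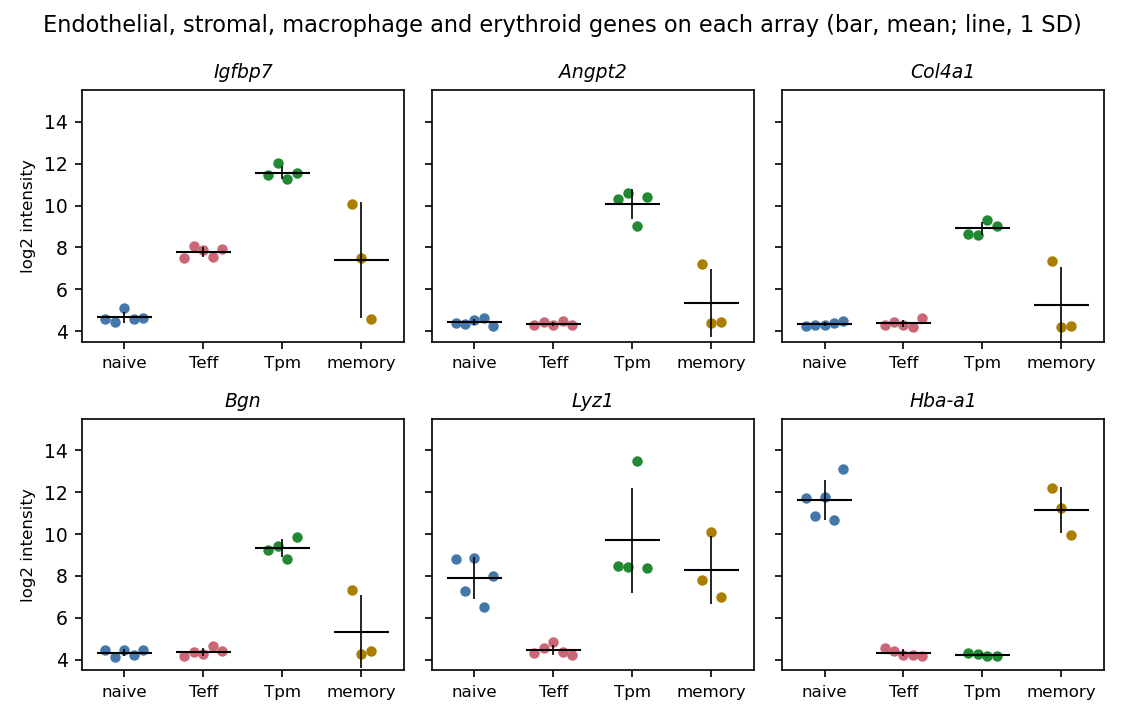
Log2 intensity (vertical axis) of Igfbp7, Angpt2, Col4a1, Bgn, Lyz1 and Hba-a1 on each of the 17 arrays, by group (horizontal axis); points are arrays, bars group means and lines 1 SD. Memory 3 lies above the other memory arrays for Igfbp7 (10.10), Angpt2 (7.23), Col4a1 (7.36) and Bgn (7.35), and Tpm 14 above the other Tpm arrays for Lyz1 (13.49).

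The other tested lists were not called against naive cells, with adjusted p between 0.0513 and 0.927. Of 18 memory CD8 T-cell genes 4 rose and 3 fell, of 17 cytotoxic granule genes 4 and 1, of 16 effector cytokine and chemokine genes 7 and 2, and of 13 NK-type receptor genes 4 and 0. Co-inhibitory receptor and exhaustion genes had 4 higher and 1 lower of 14, co-stimulatory receptor genes 2 and 5 of 14, T-cell fate transcription factors 6 and 1 of 20, chemokine receptor and trafficking genes 1 and 2 of 14, and residency and TGF-beta response genes 3 and 6 of 15. For fatty acid oxidation genes the counts were 3 and 0 of 18, for cholesterol synthesis 2 and 0 of 18, for ribosome biogenesis 0 and 0 of 17, for apoptosis regulators 4 and 1 of 21, and for CD8 T-cell identity genes 0 and 1 of 12. Markers of dendritic cells (0 of 11), macrophages (0 of 12), B cells (0 of 7) and hepatocytes (0 of 4) had no called member in these counts. Macrophage markers varied between naive arrays, with list means of 0.898 for naive 1 and 1.04 for naive 11 and from -0.80 to -0.459 on the others. Neutrophil markers had 3 of 8 lower, NK cell markers 1 higher and 1 lower of 6, and CD4 and regulatory T-cell markers 1 and 1 of 5. Without single arrays some of these lists passed: the residency list without memory 3, memory 5, memory 9, naive 13, Tpm 14, Tpm 15 or Teff 16 (adjusted p between 0.0226 and 0.0497), NK-type receptors without naive 2, memory 5 or memory 9 (between 0.0236 and 0.0368), neutrophil markers without naive 2 (0.0383) or naive 12 (0.00525) and macrophage markers without Tpm 14 (0.0418). These passes used the preset correlation, and an estimated correlation was not tried without single arrays. Adjusted over the list alone, 15 immediate early genes and 7 residency genes were lower and 5 co-inhibitory genes higher. The other counts against naive cells stayed as given.

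Of the genes named in any case, Tbx21, which encodes T-bet, rose by 1.70 (adjusted p = 3.2e-05), the adhesion receptor Cd44 by 1.35 (adjusted p = 0.00105) and the interleukin-2 receptor gene Il2ra by 1.18 (adjusted p = 0.000187). Il18r1 fell by 1.99, the lymph node homing receptor Ccr7 by 1.69 and the interleukin-7 receptor gene Il7r by 1.68. The differences of Cxcr6 (1.06, adjusted p = 0.163), Prf1 (-0.84, adjusted p = 0.141), Eomes (-0.68, adjusted p = 0.188) and Ifng (-0.67, adjusted p = 0.134) did not pass the test. Cd274, which encodes PD-L1, differed by 0.91 (adjusted p = 0.00758), less than the minimum, and passed it without Tpm 4 (1.00) or without Tpm 15 (1.05). Klrg1 was not above background in either group, and Pdcd1 was above it on 2 naive and 0 Tpm arrays. Gzmb had 1 probe, which was not above background on any array, those of Teff included. This probe alone cannot show whether Gzmb was expressed. Scaling each array to its median moved the split against naive cells to 670 higher and 225 lower, with 0.13 for the median gene.

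**Figure D3:**
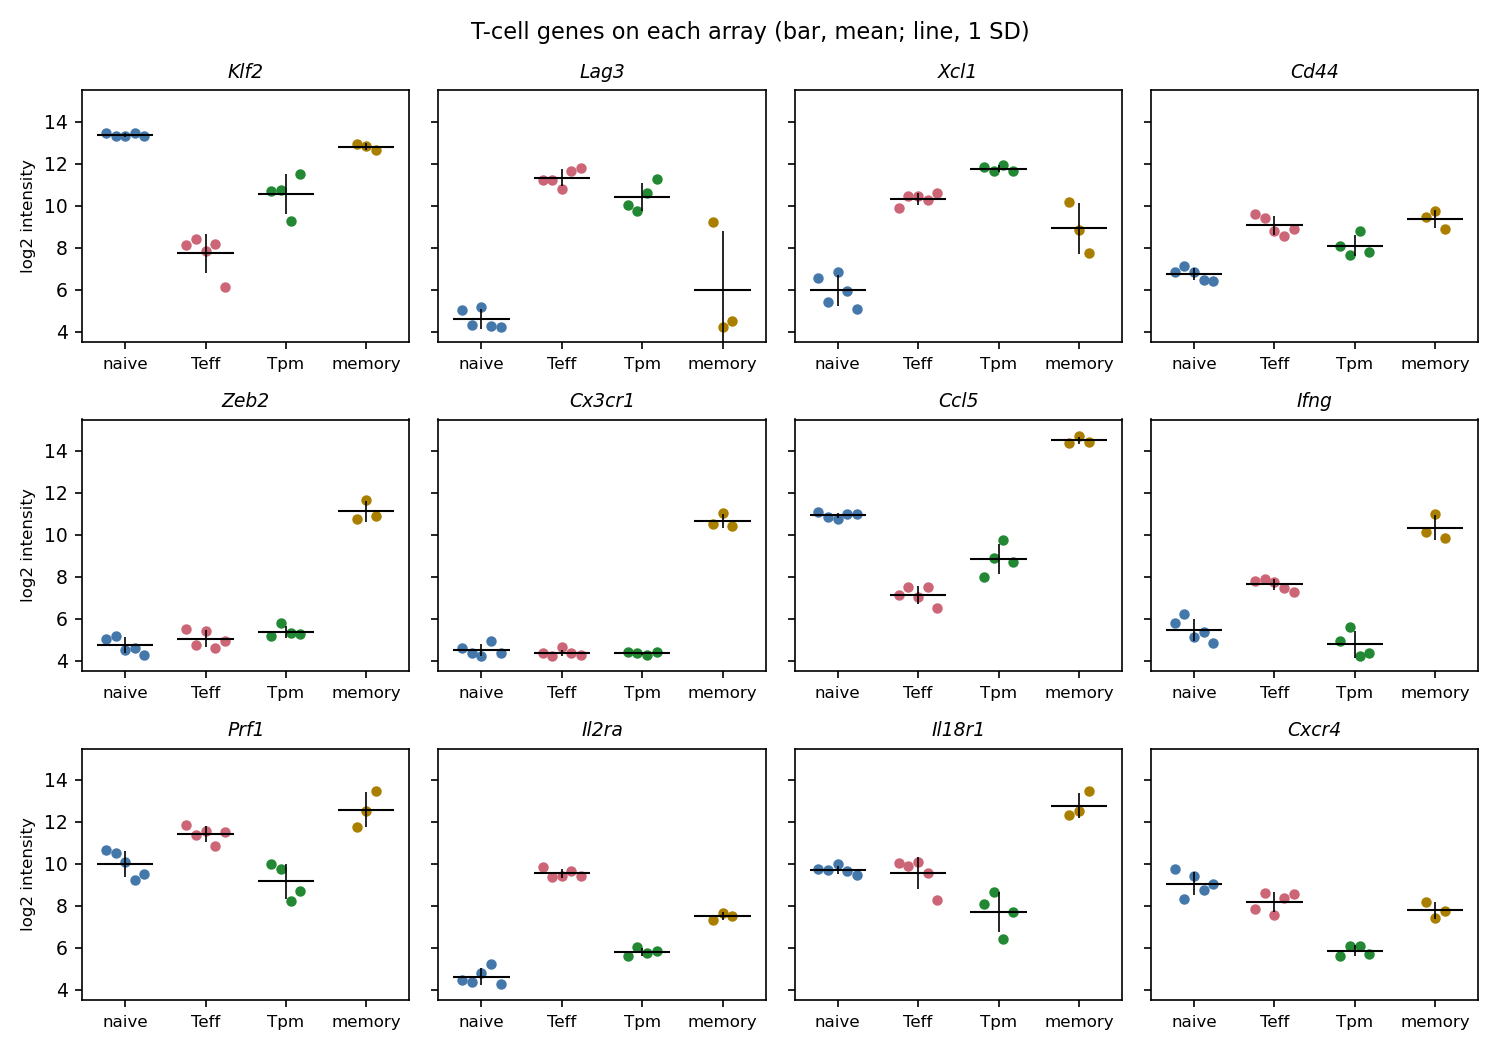
Log2 intensity (vertical axis) of 12 T-cell genes on each of the 17 arrays, by group (horizontal axis); points are arrays, bars group means and lines 1 SD. Xcl1 is highest in Tpm (11.78) and Cx3cr1 lies between 10.41 and 11.02 on the memory arrays.

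Compared with Teff, the question was how T cells primed by LSEC differed from those activated by dendritic cells. Tpm held lower levels of most measured genes of cell division, glycolysis and cholesterol synthesis, and of Il2ra, Prf1 and Ifng. Of 18 interferon-gamma response genes 11 were higher (adjusted p = 0.0901 with an estimated correlation), and of 21 type I interferon response genes 8 were (adjusted p = 0.424 with an estimated correlation). All 18 measured cell division genes fell (adjusted p = 1.13e-11; adjusted p = 0.0888 with an estimated correlation), among them the kinases Aurkb (-2.99) and Aurka (-2.76) and the topoisomerase Top2a (-2.80). Il2ra fell from 9.54 ± 0.20 (SD, n = 5) to 5.81 ± 0.18 (SD, n = 4), by 3.73 (adjusted p = 4.48e-10). In all, 792 genes were higher and 819 lower in Tpm.

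Among the largest falls were those of the fatty acid desaturase Scd1 (-5.59), Mgarp (-5.45), Tg (-4.91), the collagen prolyl hydroxylase P4ha2 (-4.89), the histone gene H2bc11 (-4.56), the co-stimulatory receptor Tnfrsf4, also called OX40 (-4.51), the aldolase Aldoc (-4.49) and the transcription factor Batf3 (-4.45). Pkp2 was at least 12.2-fold lower, the secreted glycoprotein Stc2 at least 11.2-fold, Muc2 at least 11.1-fold and Acsl6 at least 9.24-fold. Their adjusted p-values lay between 7.03e-13 (Muc2) and 2.05e-07 (Mgarp).

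Glycolysis genes fell in 14 of 16 cases with 0 rises (adjusted p = 3.24e-12; adjusted p = 0.0258 with an estimated correlation). Examples were Pfkp (-3.01), Aldoa (-2.73), Pgam1 (-2.54) and the glucose transporter Slc2a1 (-2.31). Of 18 cholesterol synthesis genes 14 fell and 0 rose (adjusted p = 2.58e-13; adjusted p = 0.00504 with an estimated correlation), with Fdps (-3.83), Cyp51 (-3.25), Lss (-3.21) and Mvd (-3.10). A second probe of Lss gave 0.11. DNA replication genes had 18 of 25 lower and 0 higher (adjusted p = 2.25e-11; adjusted p = 0.012 with an estimated correlation), among them Tk1 (-2.33), the DNA ligase Lig1 (-2.22), Mcm10 (-2.19) and Cdc45 (-2.00). Genes of the amino acid response and one-carbon metabolism had 8 of 17 lower and 0 higher (adjusted p = 2.08e-05; adjusted p = 0.116 with an estimated correlation). Chac1 fell by 3.35, Ddit4 by 3.04, Asns by 2.83 and Trib3 by 2.48. Without Tpm 7 the differences were -2.23 for Pfkp, -2.20 for Top2a and -1.74 for Tk1, and without Tpm 14 that of Ddit4 was -3.73.

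**Figure D4:**
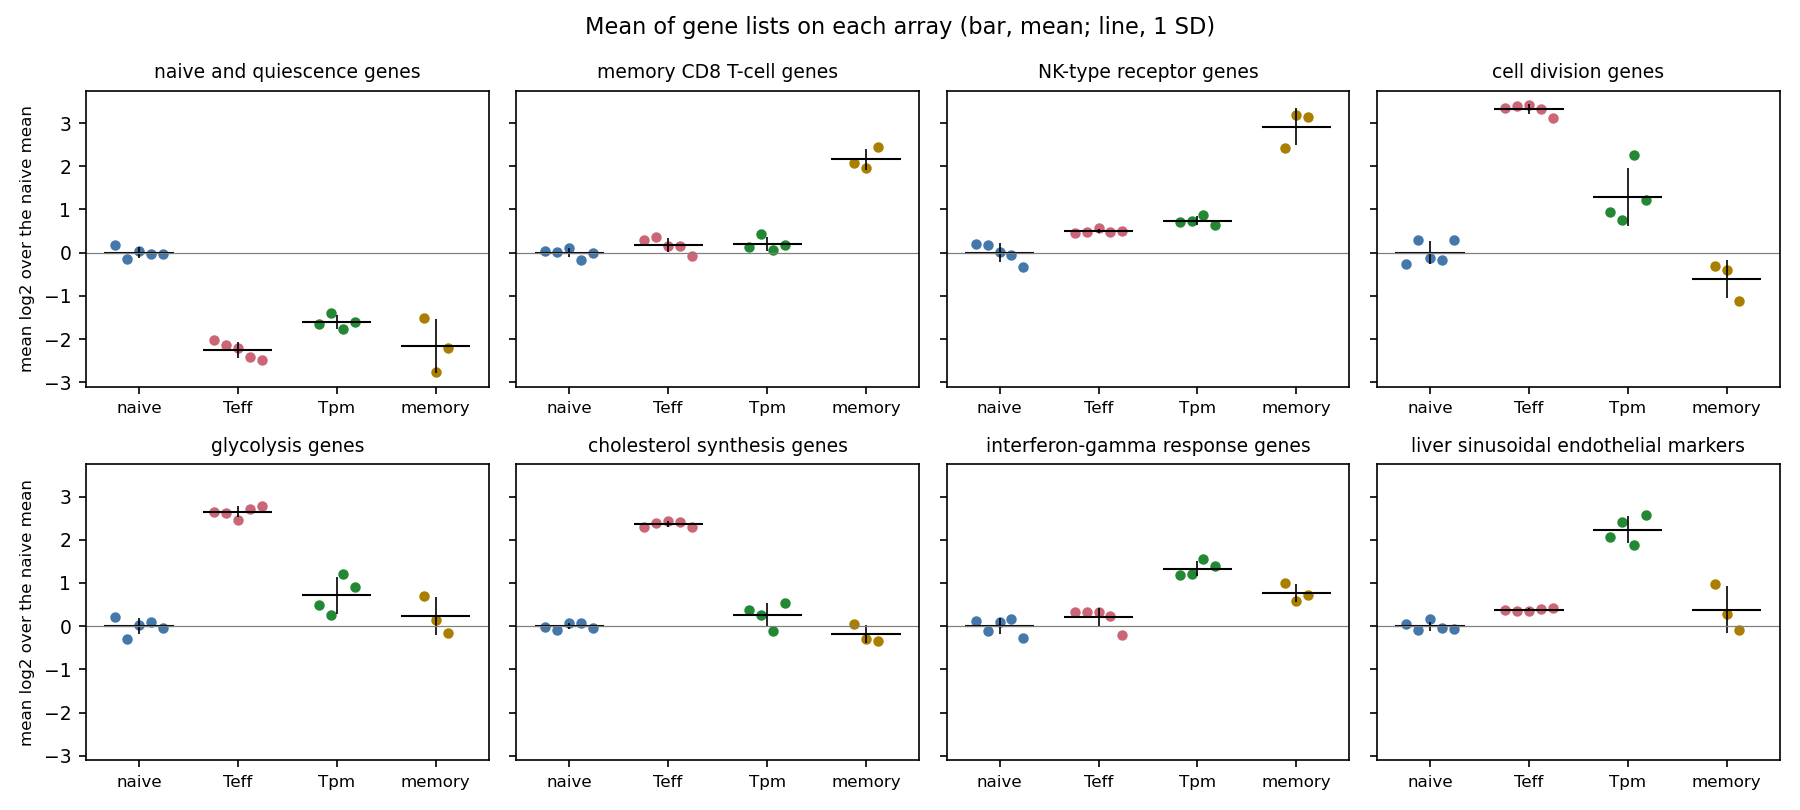
Mean of 8 gene lists on each of the 17 arrays as log2 difference from the naive mean (vertical axis), by group (horizontal axis); points are arrays, bars group means and lines 1 SD. Cell division, glycolysis and cholesterol synthesis genes are highest on the 5 Teff arrays, memory CD8 and NK-type receptor genes on the 3 memory arrays, and liver sinusoidal endothelial markers on the 4 Tpm arrays.

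Among genes higher in Tpm than in Teff, Ifi213, of a family of interferon-inducible DNA-sensing proteins, rose from 5.36 ± 0.21 (SD, n = 5) to 11.06 ± 0.35 (SD, n = 4), by 5.70 (adjusted p = 2.09e-12). Cxcl9 rose by 5.59, Serpina3f by 4.67, Calhm6 by 4.53 and the sialyltransferase St6galnac3 by 4.19, and Ubd was at least 30.7-fold higher. Of 18 interferon-gamma response genes 11 rose and 0 fell (adjusted p = 7.07e-05; adjusted p = 0.0901 with an estimated correlation), with Gbp2 (2.03) and Irgm2 (1.74). Of 21 type I interferon response genes 8 rose and 0 fell (adjusted p = 0.00107; adjusted p = 0.424 with an estimated correlation). Ifit3 was at least 9.13-fold higher, Oasl2 at least 5.61-fold and Rsad2 at least 3.97-fold, while a second probe of Oasl2 gave -0.01. Klf2 rose by 2.82, Ly6c1 by 2.64, Xcl1 by 1.44 and the interleukin-6 family receptor subunit Il6st by 1.97. The immediate early list was not called against Teff (3 of 21 higher, 5 lower, adjusted p = 0.58), with Egr3 (2.25) and Egr2 (1.88) among the former and Junb (-2.06) among the latter.

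Endothelial and stromal genes were higher in Tpm than in Teff as well: 13 of 20 liver sinusoidal endothelial markers rose and 1 fell (adjusted p = 3.61e-08; adjusted p = 0.081 with an estimated correlation), and 7 of 10 stromal markers rose and 0 fell (adjusted p = 3.62e-07; adjusted p = 0.0888 with an estimated correlation). Angpt2 was at least 39.7-fold higher, Bgn at least 23.4-fold, Col4a1 at least 17.5-fold, Plvap at least 9.73-fold and Fcgr2b at least 8.22-fold. The marker that fell was the scavenger receptor Stab1, by 1.80, which was picked after its values were seen. Igfbp7 rose by 3.79 and the matrix-associated factor Ccn2 by 4.71. Of 12 macrophage markers 3 rose and 0 fell (adjusted p = 0.0378; adjusted p = 0.634 with an estimated correlation). Lysozyme genes were among them, with Lyz1 (5.23) and Lyz2 (at least 9.04-fold), and the third was Mpeg1 (2.75), whose call was lost without Tpm 14 (1.87, adjusted p = 0.0566). Slpi rose by 4.88. Without Tpm 14 the call of the macrophage list was lost (adjusted p = 0.286), and likewise without Teff 17 (adjusted p = 0.0626). For Lyz1, Tpm 14 stood at 13.49 and the other Tpm arrays between 8.40 and 8.47, and for Lyz2 at 10.92 against 6.06 to 7.70. Without Tpm 14 the differences from Teff were 3.95 for Lyz1 and 2.54 for Lyz2, and without Tpm 15 that of Lyz2 was 4.16.

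Of the genes named in any case, Prf1, which encodes perforin, fell by 2.27 (adjusted p = 0.000304), Ifng by 2.85 (adjusted p = 2.84e-06) and Il18r1 by 1.85 (adjusted p = 0.00201), and the Fas ligand gene Fasl fell by 2.72. Eomes rose by 1.57 (adjusted p = 0.00285) and Cd274 by 1.43 (adjusted p = 0.000144). Cd44 (-0.98, adjusted p = 0.00982) and Il7r (-0.74, adjusted p = 0.0399) stayed under the minimum difference. Cd44 passed it without Tpm 14 (-1.21), Teff 10 (-1.05), Teff 16 (-1.10) or Teff 17 (-1.02). Tbx21 (0.32), Ccr7 (-0.41) and Cxcr6 (-0.76) did not pass the test. Klrg1 was not above background in Tpm or Teff, and Pdcd1 was above it on 0 Tpm and 3 Teff arrays, so neither could be compared. The memory CD8 list (4 of 18 higher, 3 lower) and the cytotoxic list (3 of 17 higher, 5 lower) were not called (adjusted p = 0.791 and 0.815); the median of the cytotoxic genes was 0.29 (0.23 with genes at their bounds), their mean -0.30 and the direction of their test downward. Adjusted over the list alone, 4 co-inhibitory genes in place of 3 and 4 fate transcription factors in place of 3 were higher, and other counts stayed as given. Scaling to the median moved the split against Teff to 378 higher and 815 lower, with -0.10 for the median gene.

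Against memory cells formed in an infection, Tpm held lower levels of most measured genes of memory CD8 T cells and of NK-type receptors. Of 18 memory CD8 T-cell genes 0 were higher and 13 lower in Tpm (adjusted p = 1.11e-11; adjusted p = 0.00421 with an estimated correlation). Zeb2, a transcription factor of terminally differentiated effector and memory cells, stood at 5.39 ± 0.29 (SD, n = 4) in Tpm and 11.12 ± 0.49 (SD, n = 3) in memory cells, a difference of -5.73 (adjusted p = 3.06e-10). Of 18 cell division genes 15 were higher in Tpm (adjusted p = 0.214 with an estimated correlation), as were Lag3 and Ctla4 from the co-inhibitory list, which was not called (adjusted p = 0.164). In all, 1017 genes were higher and 547 lower in Tpm than in memory cells.

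Among genes lower in Tpm, the chemokine Ccl5 differed by -5.67, Ifng by -5.54, the granzyme Gzmm by -5.22, Il18r1 by -5.05, the vesicle docking factor Sytl2 by -4.94 and Rap1gap2 by -4.82. Below background in Tpm were S1pr5, a receptor that guides lymphocytes along sphingosine-1-phosphate (at least 77.5-fold lower), Klrg1 (at least 63.9-fold), the fractalkine receptor Cx3cr1 (at least 56.6-fold) and the interleukin-18 receptor subunit Il18rap (at least 27.0-fold), for which a second probe gave -0.56. Their adjusted p-values lay between 8.83e-13 (Cx3cr1) and 6.99e-07 (Il18r1).

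NK-type receptor genes were lower in 9 of 13 cases and higher in 0 (adjusted p = 2.53e-08; adjusted p = 0.012 with an estimated correlation). Besides Klrg1, Klra3 fell by 4.50, Klre1 by 3.82, and Klrc1 was at least 16.0-fold lower. Cytokine receptor genes had 6 of 21 lower and 1 higher (adjusted p = 7.14e-05; adjusted p = 0.012 with an estimated correlation), and chemokine receptor and trafficking genes had 7 of 14 lower and 2 higher (adjusted p = 2.07e-05; adjusted p = 0.012 with an estimated correlation), with Cxcr6 lower (-2.65) and Ccr7 higher (2.81; 3.51 without memory 3 and 2.18 without memory 5). Of 17 cytotoxic granule genes 6 were lower and 1 higher (adjusted p = 0.00547; adjusted p = 0.0591 with an estimated correlation), with Prf1 (-3.41) and Fasl (-3.39). Of 16 effector cytokine and chemokine genes 6 were lower and 3 higher (adjusted p = 0.00521; adjusted p = 0.0832 with an estimated correlation); Tnfsf14 differed by -3.41 and Xcl1 by 2.85. From the memory list, Ly6c1 (-3.54) and Id2 (-2.86) were lower. Markers of NK cells, which share receptor genes with memory CD8 T cells, were lower in 4 of 6 cases (adjusted p = 2.07e-05; adjusted p = 0.0451 with an estimated correlation), among them Klrb1c (-3.05). Adjusted over the list alone, 8 chemokine receptor genes and 7 effector cytokine genes were lower, 4 effector cytokine genes and 12 DNA replication genes were higher, and counts of the other called lists stayed as given.

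Of 18 cell division genes 15 were higher in Tpm and 0 lower (adjusted p = 2.57e-07; adjusted p = 0.214 with an estimated correlation), with Nusap1 (3.20), the survivin gene Birc5 (3.06) and Top2a (2.82), and a second probe of Nusap1 gave -0.13. Without memory 9 Nusap1 differed by 2.49, and without memory 3 Birc5 by 3.71 and Top2a by 3.52. Of 25 DNA replication genes 11 were higher (adjusted p = 4.01e-05; adjusted p = 0.0789 with an estimated correlation), with Mcm10 (2.64), Cdc6 (2.39), Cdc45 (2.16) and Uhrf1 (1.97). Kit (4.79), Hivep3 (4.73), Cldn10 (4.48), Synpo (4.44), Lag3 (4.44), Cxcl9 (4.43) and Ubd (4.42) were, with Angpt2 (4.73), among the largest differences upward. The lipase Lpl was at least 5.54-fold higher, Gucy1a1 at least 5.37-fold, Hmgn3 at least 5.30-fold and Renbp at least 5.08-fold. Tpm 14 carried part of this, as without it the fitted differences fell from 3.55 to 2.62 for Lpl and from 3.39 to 2.66 for Hmgn3. Among co-inhibitory genes, where 5 of 14 were higher and the list was not called (adjusted p = 0.164), were Tox (3.68), Cd200 (3.43) and Ctla4 (3.09). From the immediate early list, which was not called (4 of 21 higher, 3 lower, adjusted p = 0.568), Egr2 (4.19) and Egr3 (3.40) were higher. On memory 3, Lag3 stood at 9.22 and Kit at 8.67, and neither was above background on memory 5 or memory 9. Without memory 3 the differences were larger, such as 6.19 for Kit, 6.11 for Lag3, 6.05 for Hivep3, 5.71 for Cxcl9, 5.57 for Igfbp7, 4.66 for Tox and 4.14 for Ctla4. Without memory 9, Igfbp7 differed by 2.78, Ctla4 by 1.82, Lag3 by 3.72 and Kit by 4.00, and without memory 5, Tox by 2.66, Lag3 by 3.58 and Hivep3 by 3.85.

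Endothelial markers were higher in 15 of 20 cases and lower in 1 (adjusted p = 3.61e-08; adjusted p = 0.081 with an estimated correlation), and stromal markers in 6 of 10 (adjusted p = 3.18e-05; adjusted p = 0.164 with an estimated correlation). Igfbp7 differed by 4.19 and Bgn by 3.99, with memory 3 at 10.10 and 7.35. The Fc receptor gene Fcgr2b, a member of the endothelial list that T cells can express too, was lower in Tpm (-3.04). Haemoglobin genes were lower, with -7.38 for Hbb-bs, and Hbb-bt was at least 123-fold and Hba-a1 at least 79.7-fold. Of 5 erythroid markers 1 was called (camera adjusted p = 0.00901, and 0.302 with an estimated correlation). The mean of this list was low on the Teff arrays too.

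Further genes named in any case were lower in Tpm than in memory cells: Tbx21 (-3.22, adjusted p = 1.85e-07), Eomes (-2.24, adjusted p = 0.000664), Il7r (-1.76, adjusted p = 0.000303), Il2ra (-1.70, adjusted p = 2.51e-05) and Cd44 (-1.28, adjusted p = 0.00488). Cd274 (0.26) did not pass the test, and Pdcd1 was not above background in either group. With arrays scaled to the median, 4525 genes were higher and 55 lower, the median gene differed by 1.09, and Cd44 (0.53) and Il7r (0.16) turned. Leaving out memory 3 and memory 5 left memory 9 as the 1 memory array, which is then assumed to vary like the other groups. In that fit 771 genes were higher and 495 lower, 938 of them shared with the 1564 genes called on all arrays.

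Teff and memory cells were each set against naive cells and against each other to place Tpm. Teff had 1416 genes higher and 1122 lower than naive cells. Among genes above background on at least 1 array of both groups, the metallothionein Mt1 (7.79), Aldoc (7.10) and Lag3 (6.74) rose most, and Ifi213 (-6.41), Klf2 (-5.64) and Cd163l1 (-5.20) fell most. Rises took in all 18 cell division genes (adjusted p = 9.24e-12; adjusted p = 0.0869 with an estimated correlation), 21 of 25 DNA replication genes (adjusted p = 1.35e-10), 15 of 16 glycolysis genes (adjusted p = 1.02e-10) and 15 of 18 cholesterol synthesis genes (adjusted p = 4.64e-10). The latter 3 lists kept their call with an estimated correlation (adjusted p = 0.00803, 0.0304 and 0.00803). Type I interferon response genes fell in 14 of 21 cases (adjusted p = 5.23e-06; adjusted p = 0.254 with an estimated correlation).

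Memory cells had 592 genes higher and 740 lower than naive cells. With the same limit, S1pr5 (6.69), Zeb2 (6.38) and Fcgr2b (6.28) rose most, and Dusp10 (-5.61), the tubulin Tubb2b (-5.47) and Crem (-5.37) fell most. A second probe of Tubb2b gave 0.03. Memory CD8 genes were higher in 13 of 18 cases (adjusted p = 4.48e-13; adjusted p = 0.00202 with an estimated correlation), NK-type receptor genes in 10 of 13 (adjusted p = 1.58e-12; adjusted p = 0.00485 with an estimated correlation) and cytotoxic granule genes in 7 of 17 (adjusted p = 9.26e-06; adjusted p = 0.00803 with an estimated correlation). Against Teff, memory cells had 1125 genes higher and 1614 lower. With the same limit again, the largest differences were those of Ccl5 (7.37), Ifi213 (6.49) and Ly6c1 (6.18) upward and of Mgarp (-5.76), Tg (-5.63) and Top2a (-5.62) downward. With arrays scaled to the median, the counts higher and lower were 1737 and 544 for Teff against naive cells, 84 and 3651 for memory against naive cells, and 103 and 5105 for memory cells against Teff. The median gene then differed by 0.19, -0.87 and -1.17.

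The changes from naive cells to Tpm were set beside those to Teff and to memory cells. Tpm and Teff came from coculture, whereas naive and memory cells were taken from spleens. Shared effects of culture can therefore add to the overlap of Tpm with Teff. Of 889 genes higher in Tpm, 512 were higher in Teff too, and of 511 lower genes 372 were lower. Independent lists of these sizes would share 123 and 56.0. Unchanged groups simulated against the same naive arrays shared 0, but such groups have few called genes, so this overlap lay near 0 by construction. It does not show how much the shared naive arrays add to the overlap. Across genes, which are not independent replicates, the differences correlated with r = 0.637, against 0.470 in the simulation, and with naive arrays split into groups of 2 and 3 with r = 0.550 to 0.614 over 20 splits. Their covariance was 0.563, against 0.0348 in the simulation. With memory cells, 195 higher and 247 lower genes were shared, where independent lists would share 51.4 and 36.9. The simulation gave 0.020 on average, again near 0 by construction. The correlation was 0.424, against 0.407 simulated and 0.327 to 0.401 over the splits, and the covariance 0.279 against 0.0348.

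Genes were then classed by their calls in Teff and in memory cells, against the same naive arrays as Tpm. These shared arrays add to the overlap, and no value without change was computed for the classes. Of 202 genes higher in both, 136 were higher in Tpm, and of 312 lower in both, 190 were lower. Of 1158 genes higher in Teff alone, 363 were higher in Tpm, whereas of 343 genes higher in memory cells alone, 58 were. Among 6993 genes called in neither, 300 were higher and 70 lower in Tpm. The difference between these shares was not tested. Tpm shared coculture with Teff and not with memory cells, so culture cannot be told apart from cell state here.

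Contrasts that share no arrays gave the following values. They still share a difference in origin, as Tpm and Teff came from coculture and naive and memory cells from spleens. An effect of culture therefore cannot be told apart from a likeness of cell state in these values. The difference of Tpm from memory cells correlated with that of Teff from naive cells with r = 0.289 (Spearman 0.293), and 70.5% of the 2538 genes called between Teff and naive cells had the same sign. The difference of Tpm from Teff was not correlated with that of memory from naive cells (r = -0.0061, Spearman 0.040), and 49.5% of 1332 genes had the same sign. Between the difference of Tpm from naive cells and that of memory cells from Teff r was -0.307, and 28.4% of 2739 genes had the same sign.

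Apart from all 3 other groups in the same direction, Tpm held 185 genes higher and 23 lower. Scaling to the median gave 180 higher and 1 lower, so the downward genes below depend on the scaling. The largest smallest differences upward were those of Angpt2 (4.73), Cxcl9 (4.43), Ubd (4.42), the collagen chaperone Serpinh1, which lay between Ubd and Bgn, Bgn itself (3.99), the endothelial receptor Robo4 (3.87), Igfbp7 (3.79) and Angptl7 (3.70). Of 20 liver sinusoidal endothelial markers 10 were among these genes, where 0.361 were expected (hypergeometric adjusted p = 1.51e-11), and of 10 stromal markers 6 were (adjusted p = 1.04e-07). Interferon-gamma response genes gave 5 of 18 (adjusted p = 0.000142) and effector cytokine and chemokine genes 3 of 16 (adjusted p = 0.0225). This test takes genes as independent. With camera at an estimated correlation the interferon-gamma list was not called against naive cells or Teff (adjusted p = 0.0591 and 0.0901). Of the Tpm contrasts the effector list was called only downward against memory cells, a call lost with an estimated correlation (adjusted p = 0.0832). The endothelial and stromal lists also lost their calls with an estimated correlation in each main contrast. For the interferon-gamma and effector genes, which cells of the coculture the RNA came from was not tested. Lower than in every other group were the chemokine receptor Cxcr4, by at least 1.92 in each contrast, Sytl2 (1.94), Il18r1 (1.85), Rora (1.48), Phf11a (1.38), Junb (2.06), Clk1 (1.32) and Crybg1 (1.40). Of these calls, Clk1 against Teff was lost without Tpm 7 (-0.95, adjusted p = 0.0675), Junb against memory cells without memory 3 (-1.72, adjusted p = 0.0514), and Crybg1 against Teff without Tpm 4, Tpm 7, Teff 16 or Teff 17 (adjusted p between 0.0518 and 0.0988). With memory 9 as the 1 memory array, again assumed to vary like the other groups, 176 genes stood apart upward and 21 downward, 171 of them shared with the 208 above.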

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

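Tests of the genes above background in memory 3, of the macrophage genes that were highest in Tpm 14, and of how endothelial genes moved over the Tpm arrays and in Teff were chosen only after the results were seen. The splits of the arrays and the test of sex were not.

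Each count of called genes was compared with other splits of the same arrays, and no other split reached it. This argues against chance as the source, but with 35 to 100 splits the comparison is coarse. It also takes the arrays as independent samples, which the labels do not state. The real split of the arrays was the 1 with as many genes, in 100 drawn splits for Tpm versus naive (1400 genes, highest other 986), in 100 for Tpm versus Teff (1611, highest other 1033) and in all 35 for Tpm versus memory (1564, highest other 663). The same held for Teff versus naive (2538, highest other 1, 100 splits), memory versus naive (1332, highest other 15, 56 splits), memory versus Teff (2739, highest other 5, 56 splits) and the genes apart in Tpm (208, highest other 9, 100 splits).

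The first pattern is the endothelial and stromal genes on the Tpm arrays, which the series describes as RNA of isolated, sorted T cells: of 30 measured members of the 2 lists, 22 were called higher in Tpm than in naive cells. Of these, 12 were above background on all 4 Tpm arrays and on no Teff array, and their mean pairwise correlation over the 4 Tpm arrays was 0.460, at the 99.88 percentile of 10000 random lists of like brightness (median -0.0175, 95th percentile 0.177); 10 of the 12 were lowest in Tpm 14. RNA of the endothelial cells of the coculture that came along with the sorted cells could account for this. Among the 12, however, Fcgr2b was brighter on the memory arrays (10.38 to 11.26) than on the Tpm arrays (6.92 to 8.65). Memory cells came from spleens, so its presence need not mark endothelial RNA. For 4 of the 22 (Stab1, Egfl7, Oit3 and Igfbp7), which were called higher in Teff than in naive cells too, RNA of the endothelial cells of the coculture alone is argued against, as Teff met dendritic cells; only Stab1 was as high in Teff as in Tpm, and Igfbp7 was 3.79 higher in Tpm, so what lies above the Teff level stays open. Expression by the Tpm cells themselves cannot be told apart, because 0 Tpm arrays came from T cells that had met no endothelial cells.

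The second pattern is memory 3. There, 33 of 33 genes (100%) that were bright in Tpm and not above background on memory 5 and memory 9 were above background. Set against them were 41 genes bright in Teff and under 7 on the log2 scale in Tpm, also not above background on memory 5 and memory 9. Of these, 10 (24.4%) were above background in memory 3. Noise of a dim array is argued against by the difference between these shares (Fisher's exact test, p = 1.73e-12). The p-value overstates this, as the test was prompted by the same values and takes genes that vary together as independent. The genes bright in Tpm also had no limit on their level in Teff. A Tpm array labelled memory is argued against by the correlation across genes. It was 0.956 with the other memory arrays and 0.933 with the Tpm mean, a difference of 0.0231. RNA of Tpm mixed into memory 3 could account for the 33 genes: they lay at a median of 20.4% (quartiles 18.2 to 29.0) of the Tpm mean for 6 endothelial and stromal genes and 14.2% (11.2 to 17.7) for the other 27. No biological explanation was tested.

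The third pattern is macrophage genes in Tpm 14, where 11 of 12 list members above background were highest among the 4 Tpm arrays, with a median excess of 2.53. The list was picked because its mean was high there and its members vary together, so this count tests no explanation. Sex of the mouse is argued against by naive 13, of male pattern, which lay at -0.889 from the rest of its group. That rest was raised by naive 1 and naive 11, of female pattern, with list means of 0.898 and 1.04 over naive cells. The other naive arrays lay from -0.80 to -0.459, with naive 13 itself at -0.681. Raised macrophage genes were thus not confined to Tpm 14. Teff 17, also of male pattern, lay at -0.208, but most members were near background on the Teff arrays, so this value decides little. RNA of macrophages in Tpm 14 cannot be told apart from expression by the sorted cells with these 11 genes, since no further value decides, and no biological explanation beyond sex was tested.

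Single arrays far from the rest of their group were searched for with Dixon's ratio (the gap to the nearest array over the range of the group). Chance gives about 1 in 20 groups. Only naive cells, Teff and Tpm were searched. The memory group (n = 3) was left out, so the search says nothing about memory 3 and memory 5. Of 9 groups of array measures 1 stood out (0.45 by chance), of 96 groups of list means 11 (4.8 by chance) and of 402 groups of named genes 28 (20.1 by chance). In Tpm 14 the share of probes above background was 35.0%, against 33.3% to 33.6% in the other Tpm arrays (ratio 0.833). Mean differences of lists from naive cells were far off in Tpm 14 for macrophage (2.17 against -0.79 to -0.38, ratio 0.861), dendritic cell (1.46 against -0.59 to -0.33, ratio 0.873) and neutrophil markers (-0.91 against -1.04 to -1.02, ratio 0.838), and in Tpm 4 for cytokine receptor genes (-0.64 against -0.36 to -0.35, ratio 0.952). In Teff 17 they were far off for cell division (3.12 against 3.34 to 3.42, ratio 0.71), amino acid response (2.45 against 1.86 to 1.94, ratio 0.861), interferon-gamma response (-0.19 against 0.24 to 0.33, ratio 0.820) and apoptosis genes (-0.11 against 0.040 to 0.087, ratio 0.758). The same was found in naive 13 for residency genes (-0.42 against 0.0020 to 0.16, ratio 0.724), in Teff 8 for neutrophil markers (-1.19 against -1.24 to -1.23, ratio 0.769) and in Teff 6 for stromal markers (0.055 against -0.011 to -0.0010, ratio 0.848).

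Among named genes, Tpm 14 was far above the other Tpm arrays for Lyz1 (13.49 against 8.40 to 8.47, ratio 0.987), Nusap1 (11.06 against 9.56 to 9.63, ratio 0.957), Rap1gap2 (ratio 0.897), Egr2 (ratio 0.860) and Pgk1 (ratio 0.838). It was far below them for Dcn (7.70 against 8.94 to 8.98, ratio 0.969), Klrb1c (ratio 0.908) and Cd163l1 (4.54 against 6.93 to 7.23, ratio 0.889), as was Tpm 4 for P4ha2 (ratio 0.921). Teff 17 stood high for H2bc11 (ratio 0.826), Stc2 (ratio 0.807) and Clk1 (10.16 against 8.85 to 9.17, ratio 0.757) and low for Klf2 (6.12 against 7.87 to 8.41, ratio 0.763), Egr3 (ratio 0.753), Egr2 (ratio 0.746) and Il18r1 (ratio 0.715). Teff 10 stood low for Ppp1r15a (ratio 0.772) and high for Mcm10 (ratio 0.739), and Teff 16 high for Il10ra (ratio 0.752). Naive 2 was low for Tk1 (ratio 0.886), Pfkp (6.72 against 8.83 to 9.12, ratio 0.881) and Rora (ratio 0.720) and high for Vegfa (ratio 0.826) and Stab1 (ratio 0.725). Naive 11 was high for Plvap (ratio 0.928) and Igfbp7 (5.09 against 4.44 to 4.61, ratio 0.735), naive 1 for Klrb1c (ratio 0.753), and naive 13 low for Ifit3 (6.87 against 9.76 to 10.70, ratio 0.756).

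Probes with no gene name, which the counts of genes leave out, held signal that differed between groups. Of these 286 were called in Tpm versus naive (89 higher, 197 lower), 350 in Tpm versus Teff (202 higher, 148 lower) and 390 in Tpm versus memory (186 higher, 204 lower).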

How the results depend on the processing

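Another background correction (offset 50), the sex pattern and the arrays numbered 12 to 17 as covariates, and leaving out both dim memory arrays were chosen after the data were seen; the other alternatives were not. Of 105 counts of called genes under alternatives, 74 lay within 1.5 times the count given and 31 did not. Counts that moved are given in the order Tpm versus naive, Teff and memory, Teff versus naive, memory versus naive, memory versus Teff, and Tpm apart, for which the counts above were 1400, 1611, 1564, 2538, 1332, 2739 and 208. Without background correction they were 544, 731, 621, 1276, 532, 1418 and 68, of which 541, 727, 618, 1273, 527, 1412 and 65 were among the genes above with the same sign. The authors' table gave 596, 795, 683, 1390, 597, 1529 and 72, and no minimum fold 2772, 3114, 2610, 4553, 2284, 4324 and 389, as its construction implies. Offset 50 gave 764 for Tpm versus naive, 989 versus Teff, 906 versus memory, 760 for memory versus naive and 98 for Tpm apart. Median scaling gave 895 for Tpm versus naive, 4580 versus memory, 3735 for memory versus naive and 5208 for memory versus Teff, and a fit of Tpm and memory alone gave 949. Without background correction 331 genes were higher and 290 lower in Tpm than in memory cells, and from the authors' values 380 were higher and 303 lower, against 1017 and 547 above. Under median scaling 7 named genes changed sign in Tpm versus memory: Cd44 (0.53), Bcl2 (0.60), Tnfrsf10b (0.51), Casp1 (0.44), Il7r (0.16), Clk1 (0.021) and Cd2 (0.11). Memory 3 and memory 5 were dim, and under this scaling the median gene lay 1.09 higher in Tpm than in memory cells, against 0.14 above; beyond this, and for the other settings, the cause was not tested. Of 5987 values of named genes under alternatives 5638 stayed on their side of the threshold, 335 lost their call, 7 gained it and 7 turned. Of 1515 values for gene lists 1407 stayed, 34 lost their call and 74 gained it. With the arrays numbered 12 to 17 as a covariate the counts were 1428, 1673, 1696, 2564, 1425, 2722 and 211, and Cxcr6 passed in Tpm versus naive (1.19, adjusted p = 0.0206). Leaving out 1 array at a time kept all 119 counts within 1.5 times: 1338 to 1475, 1487 to 1810, 1344 to 1924, 2439 to 2600, 1097 to 1705, 2560 to 3066 and 171 to 229. The highest count of Tpm versus memory came without memory 9 and the lowest without memory 5. Correlations of Tpm versus naive with Teff versus naive then ran from 0.589 to 0.659 and with memory versus naive from 0.369 to 0.453, and of Tpm versus memory with Teff versus naive from 0.247 to 0.324. That of Tpm versus Teff with memory versus naive ran from -0.0147 to 0.0105, and the shares of the same sign from 67.1% to 72.4% and from 48.2% to 51.7%. Of 6788 values of named genes 114 lost and 6 gained their call, and of 1623 list values 3 lost and 21 gained it. No paired analysis was possible because the groups share no replicate numbers, and slides as a block were not run, because the files used here name none. Signal over background limited memory 5 most, with 5408 genes above background against 7522 to 8868 on the others.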

Other observations

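Gene families in this part were picked after the results were seen, and no test was made of them beyond that of their members. Replication-dependent histone genes, which are transcribed in S phase and mostly lack a poly(A) tail, were lower in Tpm than in Teff in 40 of 51 cases and higher in 0, and higher in Teff than in naive cells in 39 and lower in 2. Memory cells had 36 lower than Teff and 0 higher. Between Tpm and naive cells 4 were higher and 7 lower, and between Tpm and memory cells 2 were higher and 19 lower. In both, the lower genes went against the direction of the cell division and DNA replication lists. The classes differed against memory cells. Most H2ac genes lay higher in Tpm, such as H2ac21 (1.90) and H2ac11 (1.51). Most H2bc, H3c and H4c genes lay lower, such as H2bc7 (-1.93) and H4c3 (-2.14). Of 15 genes induced at low oxygen, 12 were higher in Teff than in naive cells and 13 were lower in Tpm than in Teff, with 0 in the other direction in both. Examples in Tpm against Teff were Ndrg1 (-4.22), the oxygen sensor Egln3 (-3.23) and the growth factor Vegfa (-2.80). In memory cells 13 were lower than in Teff, and in Tpm 3 were higher than in naive cells. The 3 measured genes of the p200 family of interferon-inducible DNA sensors were Ifi213, Ifi214 and Mndal. All were lower in Teff than in naive cells (-6.41, -3.53 and -2.45) and higher in Tpm than in Teff (5.70, 3.70 and 2.54). Between Tpm and naive cells 0 of 3 were called, with differences of -0.71, 0.17 and 0.10.

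Within groups, the arrays varied along a shared direction. After subtraction of the group means, the first principal component held 30.5% of the variance, with scores of 46.8 for Tpm 7, 29.2 for naive 2 and 24.2 for memory 9, and of -35.0 for Tpm 14 and -26.5 for Tpm 15. All arrays numbered 12 to 17, from naive, Tpm and Teff, had scores from -35.0 to -13.7. Arrays numbered 1 to 11, which hold all memory arrays, ran from -22.3 to 46.8. The arrays of male pattern, naive 13 (-13.7), Tpm 14 (-35.0) and Teff 17 (-18.3), are among the former, beside others of female pattern. Xist had the largest loading at the positive end (0.065) and Eif2s3y at the negative end (-0.058), both genes of the sex chromosomes. Sex pattern and array number thus overlap, and the cause of this direction was not tested. The deviations of naive 2 and Tpm 7 correlated across genes with r = 0.623, and those of naive 2 and Tpm 15 with r = -0.553.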
